A study of Mus musculus with 21 samples.

How the data were processed

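Gene expression was measured in 21 samples of mouse prostate tumour, taken from the anterior prostate, on Illumina bead arrays (1 array per sample, several arrays per chip). Per the labels' protocols, total RNA was extracted with a magnetic bead kit, its quality was checked on a Bioanalyser, and it was amplified and biotin labelled with an Illumina TotalPrep kit. The submitters' processing notes name BeadStudio and lumi with no version and no role. Groups were taken from the sample titles and genotype labels: NP (8 arrays), NPK (8 arrays, with no stage in the labels), NPK at 1 month (3 arrays, early stage) and NPK at 3 months (2 arrays, late stage). The labels give each sample its own ID number and do not otherwise settle whether the samples came from separate animals, so p-values measure the spread between these samples.

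Intensities and processed values were both used. The deposited intensity table holds a linear bead intensity per probe for 45126 probes, background-subtracted by the authors, as seen from values below 0, and not normalized between arrays. It gave no detection p-values and no control probes here. The deposited value table holds the authors' processed values on a log2 scale. Set against the intensities above 3000, these values kept the order of the probes within each array (Spearman's rho 1.00) and had slopes of 0.946 to 1.07 against log2 intensity; their transform and centring stay unknown. Their upper quartile was 8.60 to 8.64 on the 16 NP and NPK arrays and 8.34 to 8.35 on the 5 arrays labelled by month, and their medians were 7.77 to 7.80 and 7.70 to 7.71. The sets were therefore taken as normalized separately, and the authors' values were used only as an alternative within each set.

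The planned background correction with control probes could not be run on the intensity table. In its place the same normal-exponential model was applied to each array with a background mean of 0 and a noise SD taken from the values below 0. An offset of 16 was added, arrays were quantile normalized, and log2 was taken. A probe counted as detected above the level that noise exceeds with a probability of 0.01. The noise SD was 8.59 to 26.1 intensity units. Probes detected on at least 3 arrays were kept (24217). The probe table paired 34767 probes with 1 gene symbol and 18 with several, and 10341 are not named here. Of the kept probes, 20192 had 1 symbol. The probe with the highest mean stood for its gene, which gave 12570 genes. Symbols were checked against a RefSeq gene table through the gene ID; 78 IDs had no match and kept their symbol. Of 420 entries in the gene lists, 334 were tested and 35 are not named in the probe table; those genes were not analysed here.

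Before groups were compared, replicates were compared with each other. Replicates 4 and 5 of NP had an SD of log2 differences of 0.129 over 3259 bright genes, none of which differed by 2-fold (0 genes). The next closest pair had 0.310 and 30 such genes. Replicates 4 and 5 of NP were counted as 1 sample, their mean, a choice made after this comparison, so that 20 samples entered the fits and NP had n = 7.

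Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all groups in 1 fit, 16 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fitted changes are differences of mean log2 values with the moderated SE. Gene lists of pathways and of cell types were fixed before the data were examined, as were the comparisons, the rule for named genes and most alternatives. Lists with at least 4 measured genes were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Where a named gene was detected on no more than 50% of the arrays of its dimmer group, a limit set after the results were seen, the fold is given as a lower bound, from the mean of the brighter group against, per array, the higher of the lowest detected level and the dim probe's own value. The rule named Etv4, Etv1 and Etv5 and other fixed genes not analysed here. It also named the 6 largest rises and falls past the threshold by fitted change, detected on most arrays of the higher group, and the 3 members with the smallest adjusted p of each called list. For NPK against the month-labelled groups these numbers were 4 and 2. The correlation of Etv4 with the RAS-MAPK genes used exact permutation tests.

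The noise SD, detection and background correction were tested on simulated intensities. The fits and camera were tested on simulated data with the real genes' means and spreads, the fits with 200 changed genes. Normalization, the choice of probes and the correlation tests were not simulated. The simulated errors were independent, with no chip effect and no correlation between genes, so the shares recovered hold only for such data. At a log2 change of 1, 74% of changed genes were recovered for NPK against NP, 25.5% for 3 months against 1 month, 54% for NPK against 1 month and 41.5% for NPK against 3 months, over 12570 genes. At a log2 change of 2 these shares were 96%, 78%, 91% and 84%. Alternatives tried were the authors' values, no background correction, median scaling, filters on dim probes, the mean of a gene's probes, fits of only the groups compared, the chip as a random block, the replicate number as a block, array weights, other variance priors, a 2-fold minimum, each sample and each chip left out, and the chips of 1 barcode series. Added after the data were seen were the near-identical arrays kept apart, gene list means of other tissues as covariates, NPK arrays rich in seminal vesicle transcripts left out, the RAS-MAPK list without Etv4 and Etv5, and the correlation with each chip's mean taken off. statmod 1.5.0 fitted the random block, and matplotlib 3.10.9 under Python 3.11.15 drew the figures.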

Results

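Prostate tumours of the genotypes NP and NPK were profiled to compare expression between genotypes and between stages of disease, in a study of ETV4 under combined PI3-kinase and RAS activation. NPK tumours were sampled without a stage in the labels (8 arrays), at 1 month, called early (3 arrays), and at 3 months, called late (2 arrays). NP tumours had 8 arrays. The number of probes detected per array was 19063 to 20405 in NP, 15855 to 18226 in NPK, 19458 to 20138 in NPK at 1 month and 19489 to 19600 in NPK at 3 months. Replicates 4 and 5 of NP differed by less than any other pair of replicates, with an SD of log2 differences of 0.129 against 0.310 for the next closest pair. They were treated as agreeing within noise and counted as 1 sample. No chip held both NP and NPK tumours, and the 5 arrays labelled by month shared 1 chip that held no other array. The number of arrays limits the precision of every value, above all for the 2 samples at 3 months. Those 2 arrays had the largest SD of log2 differences of all replicate pairs, 0.844 against 0.702 for the next largest. Between them 386 of 3259 bright genes differed by over 2-fold.

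The comparison of NPK with NP asked which genes differed between the genotypes. Etv4, an ETS transcription factor of the PEA3 family, rose at least 3.93-fold in NPK (fitted log2 change 2.14 ± 0.33 SE, limma adjusted p = 0.000114, n = 8 and 7). It was detected on 8 of 8 NPK and 4 of 8 NP arrays. Every NPK sample lay above every NP sample, but narrowly, with the lowest NPK value at 6.75 and the highest NP value at 6.67. Etv5, a second member of the family, rose 2.62-fold (1.39 ± 0.24 SE, adjusted p = 0.000278), again without overlap between samples; its other probe gave 0.77. Etv1, the remaining member, had a change of 0.06 ± 0.40 SE that did not pass (adjusted p = 0.924), and its other detected probes gave 0.67 and 1.02. By chip, the mean of Etv4 was 5.46 and 5.77 on the chips of NP, and 7.96, 7.92 and 6.75 on those of NPK. The chip with 6.75 held 1 array. The largest rises by fitted change were those of Svs5 (51.5-fold), Svs4 (at least 39.0-fold), Fn1 (17.0-fold), Svs1 (at least 10.8-fold, detected on 2 of 8 NP arrays), Cpxm1 (15.5-fold) and Col1a1 (14.6-fold). The fold of Svs4 is given as a lower bound because its probe was the brightest of all on 1 NPK array, not because of the limit on detection. Fn1 encodes fibronectin and Col1a1 a chain of type I collagen, and the Svs genes encode secretory proteins of the seminal vesicle. Other probes of Fn1 changed by 1.92, 1.62 and 0.08 on the log2 scale, against 4.09 for the probe used. The largest falls by fitted change were those of Scgb1c1 (at least 8.80-fold lower), Cxcl13 (16.1-fold lower), Pkd2l1 (at least 7.79-fold lower), Fam25c (11.4-fold lower), Cstdc5 (9.01-fold lower) and Upk3a (at least 5.56-fold lower). Scgb1c1 and Pkd2l1 were each detected on 1 of 8 NPK arrays and Upk3a on 2. With a sample left out, Svs5 was 39.2-fold to 79.7-fold, Svs4 at least 26.5-fold to 58.9-fold and Svs1 at least 6.15-fold to 16.8-fold higher, and Pkd2l1 at least 6.98-fold to 11.8-fold lower. Cxcl13 encodes a chemokine that attracts B cells, and Upk3a a uroplakin of urothelial membranes.

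**Figure D1:**
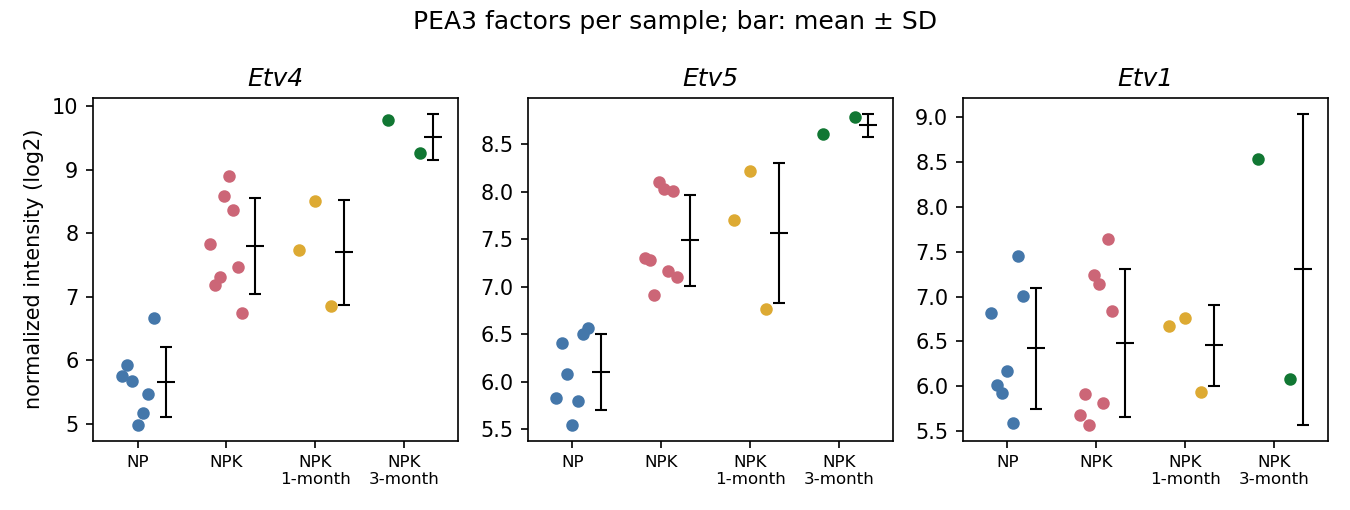
Normalized intensity (log2) of Etv4, Etv5 and Etv1 in each sample of the groups NP, NPK, NPK at 1 month and NPK at 3 months; points are samples, with the near-identical NP replicates as 1 point, and bars are the mean ± SD. Etv4 had a mean of 5.66 in NP, 7.80 in NPK, 7.70 at 1 month and 9.52 at 3 months.

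Of the genes known to respond to RAS-MAPK signalling, 14 of 19 rose in NPK, Etv4 and Etv5 among them, 1 fell and 4 did not pass, with the same counts adjusted over the list alone. Phlda1 rose by a log2 change of 1.62, Ccnd1 (cyclin D1) by 1.64 and the receptor gene Epha2 by 1.49. The list was called by camera (adjusted p = 2.54e-07), with adjusted p = 0.0850 with an estimated correlation. Without Etv4 and Etv5, 12 of 17 rose and 1 fell (adjusted p = 1.67e-06, and adjusted p = 0.0990 with an estimated correlation). Cell cycle genes followed, with 17 of 25 higher and 1 lower, and the same counts adjusted over the list alone. E2f1 rose by 1.58, and Cdk1 by 1.59, and Birc5 rose 2.83-fold; the list had adjusted p = 9.50e-07, or adjusted p = 0.410 with an estimated correlation. Of the cholesterol and fatty acid synthesis genes, 9 of 13 rose and 2 fell, also when adjusted over the list alone. The sterol enzyme genes Sqle (1.60) and Cyp51 (1.49) were among those higher, while Scd1, a fatty acid desaturase gene, fell by 1.78. This list had adjusted p = 0.00138, and adjusted p = 0.217 with an estimated correlation. Immediate early and handling stress genes rose in 7 of 11 cases and fell in 1, also when adjusted over the list alone. Ccn1 rose by 2.06 (other probes 0.87 and 1.03) and Junb by 1.11, and Jun fell by 1.26 (list adjusted p = 0.00523, and adjusted p = 0.264 with an estimated correlation); without the chip of NP 1 to 5 the list had adjusted p = 0.0634. Of the inflammatory cytokine genes, 4 of 17 rose and 1 fell, with the same counts adjusted over the list alone. Lif rose by 1.33 and Il1a at least 2.88-fold, and Csf1 fell by 1.04 (list adjusted p = 0.0301, and adjusted p = 0.611 with an estimated correlation). The call of the cytokine list was lost without NP replicate 2 (adjusted p = 0.0529) and without NPK replicates 1 (0.0916), 2 (0.0511), 6 (0.0585) or 8 (0.0508). It was also lost with the stricter detection filter (adjusted p = 0.119) and without the chips of NP 1 to 5 (0.160) or NPK 6 and 7 (0.0562), with medians of 0.38 to 0.62 against 0.49.

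Of the lists of stroma and vessels, 5 were called higher in NPK with the preset correlation and 0 with an estimated one. Of the endothelial genes, 11 of 12 rose (12 adjusted over the list alone), among them Eng (1.22), Emcn (1.38) and Vwf (1.01), with adjusted p = 7.68e-07, or adjusted p = 0.217 with an estimated correlation. Matrix protease and remodelling genes rose in 8 of 16 cases (9 adjusted over the list alone), with Mmp2 at 2.04, Lox at 2.10 and Plaur at 1.66. Fibroblast genes rose in 5 of 12 cases (6 adjusted over the list alone), with Col5a1 at 2.37 and Col6a1 at 1.90. Other probes changed by 1.51 and 0.36 for Col6a1. Mesenchymal transition genes rose in 5 of 15 cases, also when adjusted over the list alone, with Sparc at 2.45 (other probes 2.63 and 0.86) and Itga5 at 1.90 (other probe 1.29). Smooth muscle genes rose in 6 of 8 cases (7 adjusted over the list alone), with Acta2 at 1.69, Actg2 at 2.70 and Myl9 at 2.10. The adjusted p was 0.00138 for the matrix, fibroblast and smooth muscle lists and 0.00940 for the mesenchymal list. With an estimated correlation the matrix list had an adjusted p = 0.264 and each of the other 3 lists an adjusted p = 0.410. The smooth muscle list, with a median of 1.69, had a median of 0.29 with the seminal vesicle and muscle means as covariates (adjusted p = 0.317) and of 0.61 without the NPK arrays rich in seminal vesicle transcripts (0.0586). With the covariates Acta2 (0.80), Actg2 (1.24) and Myl9 (0.76) did not pass. The fibroblast list lost its call on the chips of 1 barcode series (adjusted p = 0.0555, 4 against 3 samples), with a median of 0.93 against 0.95.

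Genes of T and NK cells fell in 7 of 10 cases (8 adjusted over the list alone), among them Nkg7, which was 3.99-fold lower, and Cd3g and Cd3e with log2 changes of -1.70 and -1.26. Genes of B and plasma cells fell in 4 of 6 cases, also when adjusted over the list alone, with Cd79b at -1.94, Mzb1 at -1.56 and Cd22 at least 1.16-fold lower. These lists had adjusted p = 0.00940 and 0.0277, and adjusted p = 0.299 and 0.410 with an estimated correlation. Without NP replicate 2 the B and plasma cell list had adjusted p = 0.0529, under median scaling 0.140 and with the stricter detection filter 0.0567. It also lost its call without the chips of NP 1 to 5 (0.0844) or NPK 1 to 5 (0.276), on the chips of 1 barcode series (0.355), with NP replicates 4 and 5 as 2 samples (0.0614) and with the covariates (0.0634). Its median of -1.03 became -0.56 without the chip of NPK 1 to 5 and -0.54 on that barcode series, and lay from -1.28 to -0.86 in the other settings just named. Seminal vesicle genes rose in 5 of 8 cases (6 adjusted over the list alone; list adjusted p = 0.00309, and adjusted p = 0.410 with an estimated correlation). That call was lost without the chip of NPK 1 to 5 (adjusted p = 0.0712). Its median of 3.23 was then 1.67. It was also lost with the covariates (0.947) and without the NPK arrays rich in these transcripts (0.138), losses built in by the use of the list's own mean. Their mean level spread widely, from 6.47 to 14.6 over the NPK samples against 4.88 to 8.16 over the NP samples. The skeletal muscle list was not called (median change 0.62, adjusted p = 0.172); its mean ranged up to 9.01 in NPK and up to 6.93 in NP. Luminal genes showed 2 higher, 3 lower and 14 not passing, and macrophage genes 1 higher, 3 lower and 9 not passing; neither list was called.

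**Figure D2:**
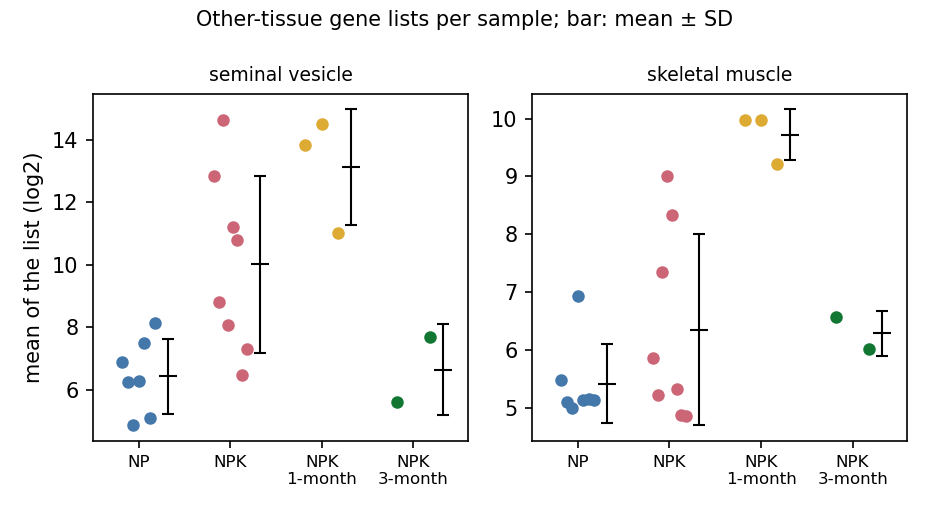
Mean log2 level of the seminal vesicle list (left) and the skeletal muscle list (right) in each sample of the groups; points are samples and bars are the mean ± SD. The seminal vesicle mean was 10.0 ± 2.84 (SD, n = 8) in NPK and 13.1 ± 1.85 (SD, n = 3) at 1 month, against 6.43 ± 1.20 (SD, n = 7) in NP and 6.65 ± 1.47 (SD, n = 2) at 3 months.

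In all, 4180 of 12570 genes differed between NPK and NP, 1888 higher and 2292 lower, and 13 of 25 gene lists were called, 11 up and 2 down, and 0 with an estimated correlation. Under median scaling in place of quantile normalization the median of all genes moved from -0.01 to -0.38, and 766 genes were higher and 5494 lower, so the balance of rises and falls is relative to the normalization. With the chip as a random block 2361 genes passed, and with the seminal vesicle and muscle means as covariates 2164 passed. Other detected probes of the called genes changed by a median of 44.9% as much as the probe used, with 72.9% in the same direction, against 77.4% and 93.3% for 3 months against 1 month within 1 chip.

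The comparison of NPK at 3 months with NPK at 1 month asked what changed between the early and the late stage, on 1 chip. The luminal, basal and interferon lists were called lower and the cell cycle list higher at 3 months with the preset correlation, and 0 lists with an estimated one. Esrp1, a splicing regulator of epithelial cells, was 54.1-fold lower (log2 change -5.76 ± 0.70 SE, limma adjusted p = 3.01e-05, n = 2 and 3). Cdh1, which encodes E-cadherin, was 5.18-fold lower (-2.37 ± 0.29 SE, limma adjusted p = 3.20e-05), or 3.06-fold without replicate 1 of the 3-month group. The SE pools the spread of all groups in the fit. The SD of Cdh1 was 1.07 at 3 months (n = 2), against 0.05 at 1 month (n = 3) and 0.12 in NPK (n = 8). The SE and p of Cdh1 thus leave out much of the spread at 3 months. Etv4 rose 3.53-fold (1.82 ± 0.58 SE, adjusted p = 0.0334), but only 1 of 5 runs with a sample left out passed. Its adjusted p was 0.232 without replicate 1 of the 3-month group (change 1.56), 0.0643 without replicate 2 (2.08), 0.0714 without replicate 1 of the 1-month group (1.84) and 0.137 without replicate 3 (1.40). Etv5 had a change of 1.14 ± 0.42 SE that did not pass (adjusted p = 0.0640; other probe 0.76), though it passed without replicate 2 of the 1-month group (1.47, adjusted p = 0.0271). Etv1 did not pass (0.85 ± 0.70 SE, adjusted p = 0.465), with other probes at 1.37 and 1.63, and was -0.38 without replicate 1 of the 3-month group.

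The largest rises at 3 months by fitted change were those of Klra4 (at least 34.8-fold), a gene of the NK cell lectin-like receptor family, Rrm2 (21.6-fold), which encodes a subunit of ribonucleotide reductase, Brinp3 (at least 16-fold), Cthrc1 (18.2-fold), Stc1 (17.9-fold) and Prkg2 (16.4-fold). Klra4 and Brinp3 were each detected on 1 of 3 arrays at 1 month. The folds were at least 13.9-fold for Klra4, at least 8.48-fold for Brinp3, 11.8-fold for Cthrc1 and 10.4-fold for Prkg2 without replicate 1 of the 3-month group. The largest falls were mostly of seminal vesicle or secretory genes. Svs1 was at least 232-fold lower, 9530003J23Rik at least 212-fold lower, Svs3b at least 118-fold lower and Pate14 at least 137-fold lower, with none of their probes detected at 3 months. Spink1 was 239-fold lower and Svs5 81.6-fold lower. Left out, replicate 2 of the 1-month group took the folds down to at least 154-fold for Svs1, 116-fold for 9530003J23Rik, 37.5-fold for Svs3b and 60.8-fold for Pate14, and to 153-fold for Spink1, and replicate 1 of the 3-month group took Svs5 to 24.3-fold. These falls had wide errors: without replicate 1 of the 3-month group none of the 6 passed, with adjusted p = 0.0560 for Svs1, 0.0591 for Spink1, 0.104 for 9530003J23Rik, 0.120 for Svs3b, 0.148 for Pate14 and 0.299 for Svs5. All but Svs1 and Spink1 also lost their call without replicate 1 or without replicate 2 of the 1-month group (adjusted p = 0.0530 to 0.107). Svs5 lost it without replicate 3 of that group (0.0556), and 9530003J23Rik (0.0785), Svs3b (0.0955) and Pate14 (0.104) without replicate 2 of the 3-month group.

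Of the luminal and general epithelial genes, 11 of 19 fell and 8 did not pass (15 lower adjusted over the list alone), with a median change of -2.24. Spint1 fell by 2.70 beside Esrp1 and Cdh1. The change of Spint1 was -1.87 without replicate 1 of the 3-month group and -3.54 without replicate 2. The list had adjusted p = 5.48e-11, or adjusted p = 0.114 with an estimated correlation. Without replicate 1 of the 3-month group the median was -0.90, and without replicate 2 it was -3.13. Basal epithelial genes fell in 4 of 12 cases and rose in 1, also when adjusted over the list alone: the keratin genes Krt17 (-2.82) and Krt14 (-2.17) fell, and the integrin gene Itga6 rose by 1.17, with other probes at 0.18 and 0.35. Krt17 was 7.05-fold lower, or 4.45-fold without replicate 1 of the 3-month group and 11.2-fold without replicate 2. Prostate secretory and androgen receptor target genes fell in 6 of 17 cases, also when adjusted over the list alone, among them Acpp (at least 5.90-fold lower), Tmprss2 (-3.83) and Slc45a3 (-3.19). These 2 lists had adjusted p = 0.0319 and 0.0233, and each had adjusted p = 0.392 with an estimated correlation. They had, without replicate 1 of the 3-month group, adjusted p = 0.0868 and 0.0962, and Krt14 (-1.21), Itga6 (0.70) and Slc45a3 (-1.58) did not pass. Tmprss2 was -1.75 in that run, and without replicate 2 it was -5.90 and Slc45a3 -4.81. Without replicate 3 of the 1-month group the basal list had adjusted p = 0.0994, and with array weights 0.0838. With the covariates the secretory list had adjusted p = 0.0553.

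Interferon response genes fell in 13 of 16 cases (15 adjusted over the list alone), with a median change of -3.11. Irf7, a transcription factor of the response, changed by -3.94, Usp18 by -3.68 and Oasl2 by -3.66 (list adjusted p = 4.83e-10, and adjusted p = 0.392 with an estimated correlation). Without replicate 1 of the 3-month group Irf7 was 9.46-fold and Oasl2 8.23-fold lower, against 15.4-fold and 12.7-fold. Other probes of Oasl2 changed by -1.84 and -3.70. Cell cycle genes rose in 23 of 25 cases (25 adjusted over the list alone), with E2f1 at 2.87, Kif11 at 3.00 and Aurkb at 2.28 (list adjusted p = 5.27e-21, and adjusted p = 0.114 with an estimated correlation). RAS-MAPK genes rose in 5 of 19 cases and fell in 1 (6 and 1 adjusted over the list alone): Spry4 rose at least 2.51-fold and Spred1 by 0.90, while Phlda1 fell by 1.16 (list adjusted p = 0.0249, and adjusted p = 0.392 with an estimated correlation). Etv4 is among the 5; without Etv4 and Etv5, 4 of 17 rose and 1 fell, and the list was not called (adjusted p = 0.0519, and adjusted p = 0.502 with an estimated correlation). In the hypoxia and glycolysis list 1 of 16 genes rose, Gapdh by 0.80, also when adjusted over the list alone. P4ha1 (1.01) and Ankrd37 (1.36) did not pass, and the list had adjusted p = 0.0467, or adjusted p = 0.764 with an estimated correlation. The RAS-MAPK list had adjusted p = 0.0868 and the hypoxia list 0.382 without replicate 1 of the 3-month group, and Spry4 (1.19), Spred1 (1.04), Phlda1 (-0.68) and Gapdh (0.43) did not pass. These lists had adjusted p = 0.0668 and 0.118 without replicate 1 of the 1-month group, and without replicate 2 the hypoxia list had 0.115. That list also lost its call on the authors' values (0.0860, median 0.45), without background correction (0.0541, median 0.57), under median scaling (0.0545, median 0.89) and with the stricter detection filter (0.0605, median 0.66). Its median in the main fit was 0.58. With the covariates the list turned (adjusted p = 0.802, median -0.079). Spred1 did not pass without replicate 2 of the 3-month group (0.76) or replicate 3 of the 1-month group (0.78), whereas Ankrd37 passed without the latter (2.14).

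Lists of other tissues were called lower too. Seminal vesicle genes fell in 5 of 8 cases (8 adjusted over the list alone), Svs6 by 6.25, and skeletal muscle genes fell in 6 of 7 cases, also when adjusted over the list alone. The muscle creatine kinase gene Ckm was at least 7.48-fold lower, Myh4 at least 1.21-fold lower and Mylpf 8.71-fold lower. Svs6 (-6.28) and Myh4 (-0.85) did not pass without replicate 1 of the 3-month group, and without replicate 2 Svs6 (-6.22) and Mylpf (-2.57) did not. Without replicate 2 of the 1-month group Svs6 (-5.41) and Myh4 (-0.87) did not pass, nor did Svs6 without replicate 1 (-5.90). Both lists had adjusted p = 0.000582, and adjusted p = 0.392 with an estimated correlation. With their own means as covariates they had adjusted p = 0.863 and 0.562, a loss that is built in. The skeletal muscle mean was 9.72 ± 0.44 (SD, n = 3) at 1 month and 6.29 ± 0.39 (SD, n = 2) at 3 months. Macrophage genes had a median change of -0.08, with 1 of 13 lower and 12 not passing, and the endothelial list was not called (median 0.25, adjusted p = 0.381).

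**Figure D3:**
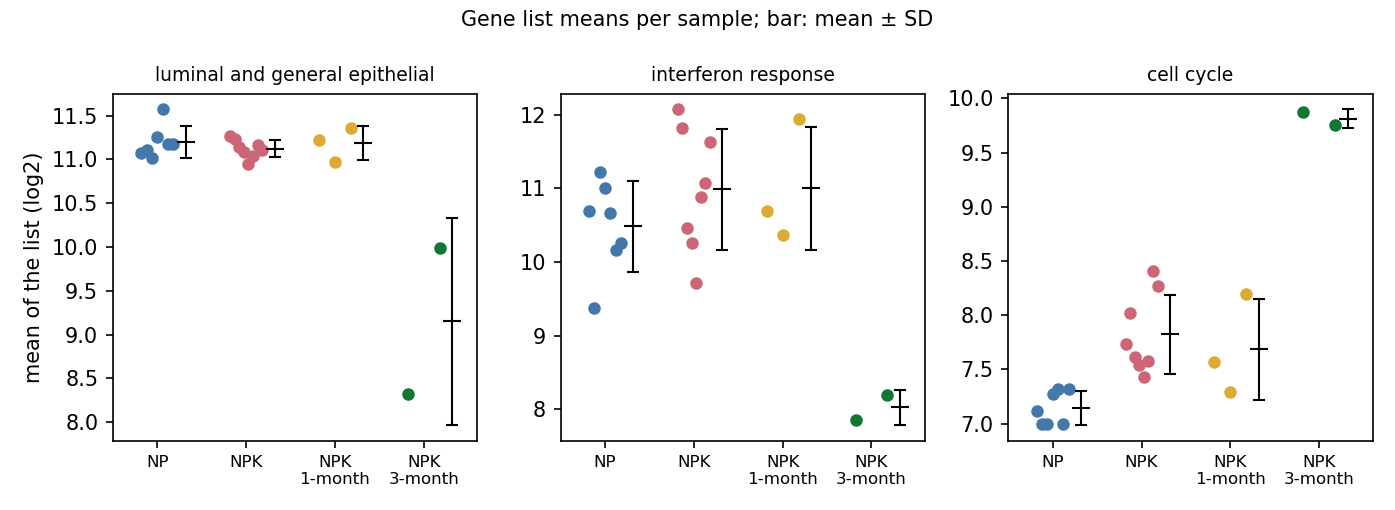
Mean log2 level of the luminal and general epithelial, interferon response and cell cycle lists in each sample of the groups; points are samples and bars are the mean ± SD. At 3 months the luminal mean was 9.15 ± 1.18 (SD, n = 2) and the interferon mean 8.03 ± 0.24 (SD, n = 2), against a luminal mean of 11.19 ± 0.19 (SD, n = 3) and interferon means from 10.37 to 11.95 at 1 month.

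Between 3 months and 1 month 2408 genes differed, 1182 higher and 1226 lower, and 9 of 25 lists were called, 3 up and 6 down, and 0 with an estimated correlation. Median scaling gave 1713 higher and 870 lower, with a median of all genes of 0.15. Without replicate 1 of the 3-month group 1108 genes and 5 lists were called, and a fit of these 2 groups alone called 1337 genes.

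**Figure D4:**
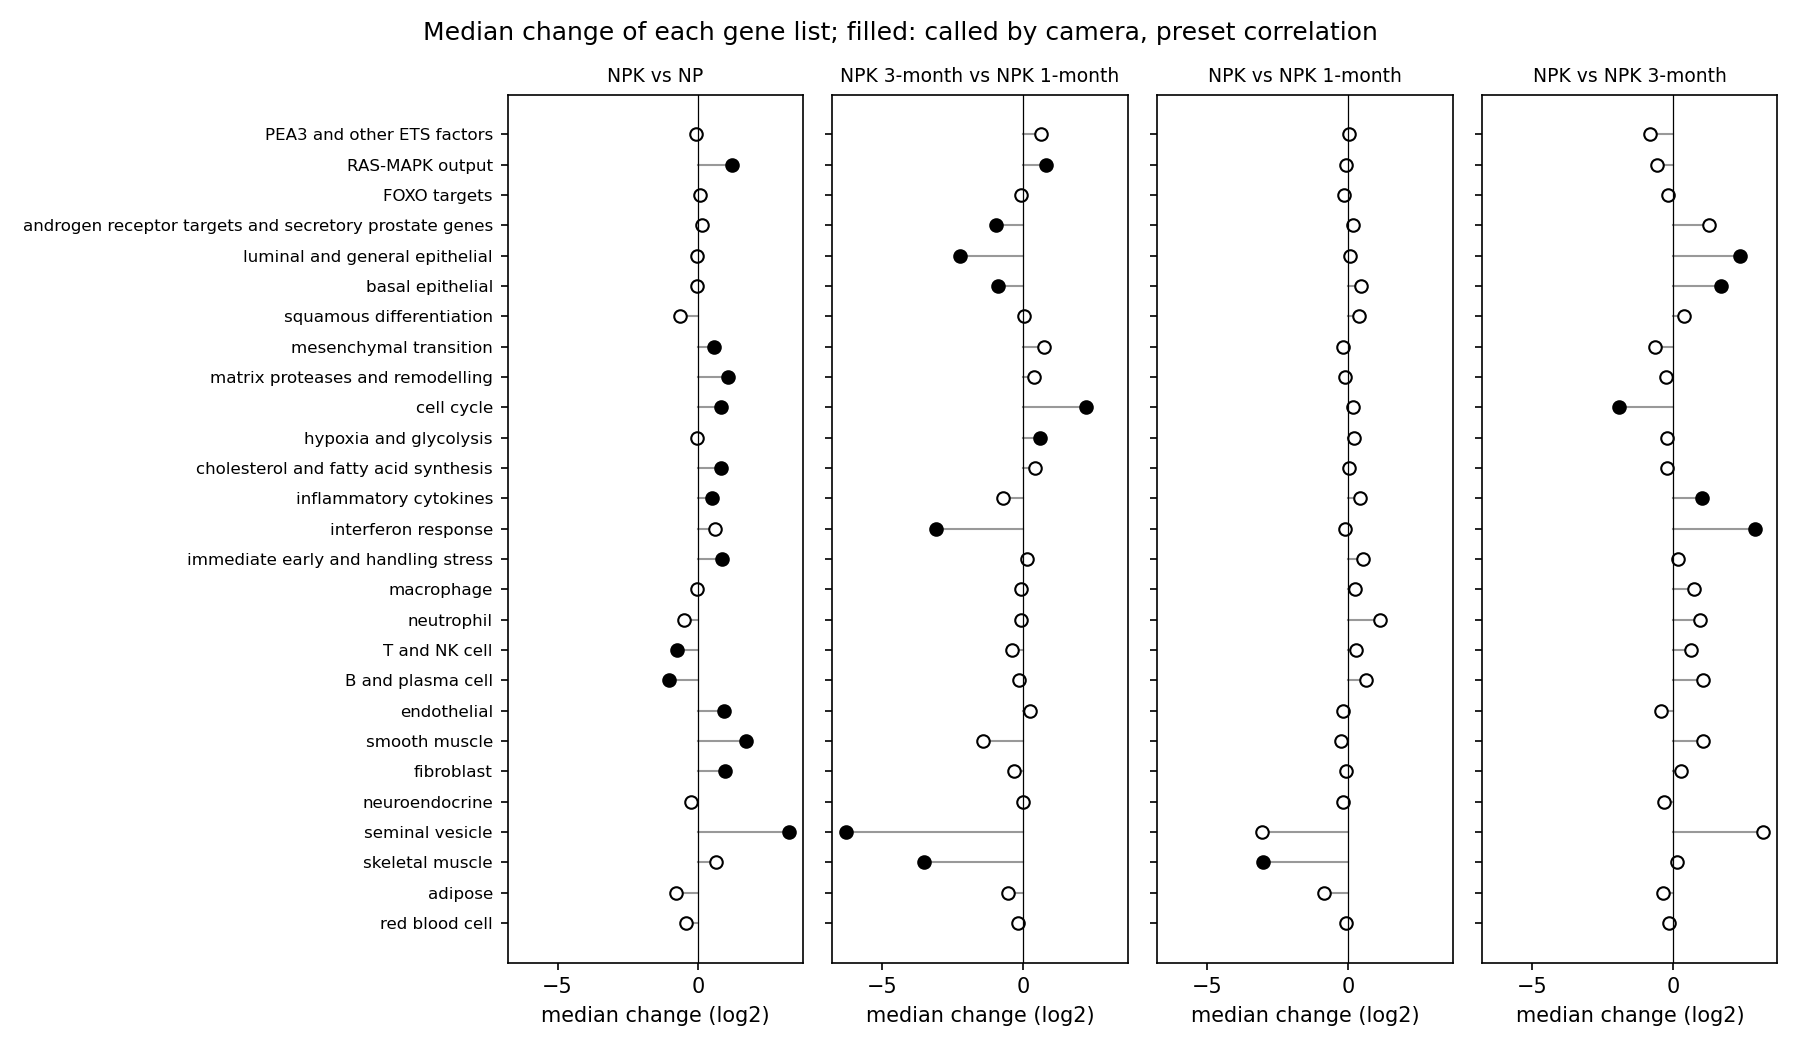
Median log2 change of each gene list in the 4 comparisons, 1 row per list; filled points were called by camera with the preset correlation and open points were not called or, with under 4 genes, not tested. The luminal list had a median of -0.06 in NPK against NP and -2.24 at 3 months against 1 month, and the cell cycle list 0.82 and 2.22.

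The changes of the genotype comparison and of the stage comparison, which share no array, were set against each other. Across 12570 genes the log2 changes had Pearson's r = -0.04 and Spearman's rho = 0.03; this is across genes, which are not independent replicates. Genes higher in both numbered 316, against 177.5 for independent lists, and genes lower in both 210, against 223.5. Under median scaling these numbers were 117 (104.4 for independent lists) and 301 (380.3 for independent lists), so the excess of shared rises depended on the normalization. Genes higher in NPK and lower at 3 months numbered 184 (184.1 for independent lists), and genes lower in NPK and higher at 3 months 115 (215.5 for independent lists). Under median scaling these were 56 (53.0 for independent lists) and 676 (748.7 for independent lists), so the size of this deficit depended on the normalization too. E2f1 rose in both comparisons, by 1.58 and 2.87, whereas Phlda1 rose by 1.62 in the first and fell by 1.16 in the second.

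NPK tumours without a stage label were also set against those at 1 month, to place them beside the early stage. Etv4 (0.10 ± 0.43 SE, limma adjusted p = 0.893, n = 8 and 3), Etv5 (-0.07 ± 0.31 SE, adjusted p = 0.888) and Etv1 (0.02 ± 0.52 SE, adjusted p = 0.978) did not pass. The other probes of Etv1 changed by -1.16 and -0.84, and that of Etv5 by -0.13. Skeletal muscle genes were lower in NPK, with 7 of 7 members lower, also when adjusted over the list alone. The list was the only 1 called of 25 (adjusted p = 0.000268, and adjusted p = 0.993 with an estimated correlation). Its adjusted p with its own mean as a covariate was 0.865, which is built in. The largest falls by fitted change were of muscle genes too: Myl1 was at least 40.6-fold lower (at least 62.7-fold without NPK replicate 4), Atp2a1 at least 17.7-fold lower, Tnnc2 at least 16.2-fold lower and Myl3 at least 14.6-fold lower, beside Mylpf (7.91-fold lower) and Ckm (at least 4.20-fold lower). Myl1 and Tnnc2 were detected on 4 of 8 NPK arrays, Ckm on 3, and Atp2a1 and Myl3 on 2. The largest rises by fitted change were of Clec2e (17.6-fold), the aminopeptidase gene Anpep (11.5-fold), Erdr1 (11.1-fold) and Cptp (at least 5.33-fold). Means in NP, NPK, 1 month and 3 months were 11.04, 11.41, 7.28 and 6.46 for Clec2e and 11.59, 12.06, 8.54 and 8.38 for Anpep. They were 11.23, 10.44, 6.97 and 5.31 for Erdr1 and 6.77, 7.94, 4.55 and 4.72 for Cptp. All 4 genes thus had lower means in both groups of the month-labelled chip than in NP and NPK. For these rises a difference between chips is not separated from stage. Other probes changed by -0.71 for Clec2e, -0.11 for Cptp and 2.42 for Erdr1, against 3.47 for the Erdr1 probe used. Cptp lost its call in 9 runs with a sample left out, namely NPK replicates 1, 2, 3, 4, 7 and 8 and each of the 1-month samples (adjusted p = 0.0636 to 0.143), and Tnnc2 without replicates 1 or 2 of the 1-month group (adjusted p = 0.0573 and 0.0526). In all, 2668 genes differed, 1357 higher and 1311 lower, while median scaling gave 690 higher and 1876 lower, with a median of all genes of -0.19. With the chip as a random block 1407 genes passed, without replicates 1 and 2 of the 1-month group 1629 and 1576 passed, and other detected probes changed by a median of 40.2% as much. Without NPK replicate 3 there were 2 lists called, and without replicate 3 of the 1-month group 5.

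Against NPK at 3 months, the NPK tumours without a stage label had the luminal, basal and interferon lists called higher and the cell cycle list lower with the preset correlation, and 0 lists with an estimated one. Etv4 (-1.72 ± 0.50 SE, limma adjusted p = 0.0106, n = 8 and 2) and Etv5 (-1.21 ± 0.36 SE, adjusted p = 0.0123) were lower in NPK (other probe of Etv5 -0.88), and Etv1 had a change of -0.82 ± 0.61 SE that did not pass (adjusted p = 0.302), with other probes at -2.53 and -2.47. Without replicate 1 of the 3-month group neither Etv4 (-1.46) nor Etv5 (-1.30) passed and Etv1 was 0.40, and without replicate 2 Etv5 (-1.12) did not pass and Etv1 (-2.05) did. The largest fitted differences toward NPK were in Fcer1g (at least 61.5-fold), which encodes a signalling chain of Fc receptors, Pglyrp1 (82.4-fold), Irf7 (43.6-fold) and H2-Q8 (at least 37.1-fold). Toward 3 months they were in Slc24a2 (at least 27.1-fold), Klra4 (at least 25.6-fold), Cthrc1 (at least 22.5-fold) and Prkg2 (34.2-fold). H2-Q8 was detected on 1 of 2 arrays at 3 months, and Slc24a2, Klra4 and Cthrc1 on 2, 3 and 1 of 8 NPK arrays. Left out, replicate 1 of the 3-month group took the folds down to 32.5-fold for Pglyrp1, 26.8-fold for Irf7 and 21.8-fold for Prkg2, and to at least 11.4-fold for Slc24a2, 10.2-fold for Klra4 and 14.5-fold for Cthrc1. Another probe of Pglyrp1 changed by 0.85 on the log2 scale, against 6.36, and another probe of Slc24a2 by -0.52, against -5.75.

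Luminal genes were higher in NPK in 15 of 19 cases, also when adjusted over the list alone, with Cdh1 at 2.61 and Spint1 at 2.40 (1.56 without replicate 1 of the 3-month group). Interferon genes were higher in 14 of 16 cases (15 adjusted over the list alone), with Oasl2 at 4.13. These lists had adjusted p = 6.01e-08 and 4.36e-07, and adjusted p = 0.376 and 0.673 with an estimated correlation. Basal genes were higher in 6 of 12 cases and lower in 1, also when adjusted over the list alone, with Krt17 at 3.05 and Ngfr at 2.59. Inflammatory cytokine genes were higher in 4 of 17 cases (2 adjusted over the list alone), with Tnf at least 14.1-fold higher and Lif at 1.70. Both lists had adjusted p = 0.0311, and adjusted p = 0.673 and 0.758 with an estimated correlation. The basal list lost its call without replicate 1 or 2 of the 3-month group (adjusted p = 0.0554 and 0.0683), and the cytokine list without replicate 2 (0.0917) or NPK replicate 1 (0.0617). Both lists lost it with the stricter detection filter (0.0889), and the cytokine list in a fit of only the 2 groups (0.0535). With that filter the basal median was 1.99, against 1.71, and the cytokine median 1.30, against 1.04. The cytokine median was 1.04 in the fit of only the 2 groups too. Without replicate 1 of the 3-month group the basal median was 1.04, and without replicate 2 it was 2.57. Cell cycle genes were lower in 24 of 25 cases (25 adjusted over the list alone), with Rrm2 at least 23.5-fold and Kif11 at least 5.94-fold lower (list adjusted p = 6.66e-13, and adjusted p = 0.376 with an estimated correlation). In all, 4920 genes differed, 2303 higher and 2617 lower, and 5 lists were called; median scaling gave 1400 higher and 4177 lower, with a median of all genes of -0.32. Without replicate 1 of the 3-month group 2736 genes passed, and with the chip as a random block 3959 passed. The 3-month arrays lay on 1 chip, which held no NPK array without a stage label.

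Within groups, the level of Etv4 was set against the mean of 17 other RAS-MAPK genes. Pearson's r was 0.38 over NP samples (exact permutation p = 0.384, n = 7) and 0.30 over NPK samples (exact permutation p = 0.454, n = 8). Spearman's rho was 0.36 (exact permutation p = 0.444) and 0.33 (exact permutation p = 0.428). Of these 2 relations, both had an adjusted p = 0.454 for r and 0.444 for rho, two-sided. Neither relation passed. Without the 2 samples farthest from the median of Etv4, which narrows its range, r was -0.80 in NP and 0.17 in NPK. Etv4 was detected on 8 of 8 NPK arrays but on only 4 of 8 NP arrays. Its NP samples lay from 4.98 to 6.67, against lowest detected levels of 5.46 to 5.63 on NP arrays. Differences below detection cannot be told from noise, so the NP correlations in this paragraph cannot decide whether a relation exists. No chip held the 6 samples needed for a correlation of its own. With each chip's mean taken off and samples permuted within chips, Pearson's r was 0.36 in NP (exact permutation p = 0.708, n = 7) and 0.25 in NPK (exact permutation p = 0.608, n = 8), both with adjusted p = 0.708. Spearman's rho was 0.43 (exact permutation p = 0.493) and 0.19 (exact permutation p = 0.704), both with adjusted p = 0.704.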

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

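The tests on the epithelial and interferon genes, on skeletal muscle genes and on other probes were chosen only after the results were seen, as were the covariates, whose bound on the count was set before their result and whose sizes were examined only after it. Of 154 groups of values tested for a lone extreme sample, 7 had one, against 7.7 from chance alone. NP replicate 6 stood apart in 3 values: its immediate early and handling stress mean was highest at 9.48 (gap 0.790 of the range), Plaur was highest at 7.94 (0.582), and Pkd2l1 was lowest at 5.34 (0.806). In NPK, Jun was highest in replicate 1 at 10.02 (0.591), Csf1 lowest in replicate 3 at 6.19 (0.552), and Spint1 lowest in replicate 5 at 13.67 (0.531). The B and plasma cell mean was highest in NPK replicate 6 at 7.32 (0.653).

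For the genes changed between NPK and NP, 1 of 100 splits of the 15 samples, the real one, gave as many (4180, highest other 168), so chance was excluded for samples drawn singly. For the gene lists called, 5 of 100 splits gave as many (13, highest other 14), so chance was not excluded. For NPK against 1 month, 1 of 100 splits of the 11 samples gave as many genes (2668, highest other 391), and 95 of 100 gave as many lists (1, highest other 13), so chance was excluded for the genes, drawn singly, and not for the lists. Chips kept whole allow only 10 splits of 5 chips and 4 of 4 chips, too few for a share under 0.05. For NPK against NP 1 of 10 gave as many genes (4180, highest other 3668, which moved only the chip of NPK 8) and 2 of 10 as many lists (13, highest other 13). For NPK against 1 month 1 of 4 gave as many genes (2668, highest other 464) and 3 of 4 as many lists (1, highest other 9).

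The luminal and interferon lists had lower medians at 3 months than at 1 month, where seminal vesicle and muscle lists were lower too. Less admixed seminal vesicle at 3 months was argued against as the whole cause. Set against the 4 NPK samples with a seminal vesicle mean of at most 10, the luminal median was still -2.40 (left-out range -3.27 to -1.26). The interferon median was -3.20 (-3.64 to -3.00). The limit of 10 lay above the seminal vesicle means at 3 months (5.61 to 7.69). Skeletal muscle played no part in the choice of these NPK samples, so admixed muscle was not tested. Those NPK samples lay on other chips than the 3-month samples, so a difference between chips could enter these medians, and the 1-month samples took no part. A lone aberrant array was argued against as the whole cause of the luminal fall, since the smaller fall with a 3-month sample left out was -0.90, but the size rests much on replicate 1, without which it was -0.90 and with which alone it was -3.13. Fewer macrophages were argued against as the whole cause of the interferon fall from 1 month, with a macrophage median of -0.084 (SE 0.20). This SE is over the 13 genes of the list and leaves out the spread between samples. By sample the macrophage mean was 9.41 to 9.98 at 1 month and 9.31 to 9.56 at 3 months. Against NPK without a stage label the macrophage median was 0.73 higher in NPK than at 3 months, though that list was not called. Stage, and other changes in cell make-up, may each account for the pattern and stay untested, with 2 samples on 1 chip.

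Seminal vesicle and skeletal muscle transcripts varied widely between NPK samples, and Svs4, among the brightest, had a mean of 13.52 in NPK and was detected on 6 of 8 NP arrays, Svs1 on 2 and Svs3b on 1. Admixed skeletal muscle was neither supported nor excluded: its genes had a median pairwise rho of 0.55 over NPK samples (lowest -0.33), but only 3 of 7 were detected on at least 4 of 8 NPK arrays, and ranks below detection decide nothing. With both list means as covariates, 1980 of 4180 genes stayed called between NPK and NP (47.4%), under the 50% that had been required beforehand, so the count did not argue against admixture as the cause of the calls. The sizes argued against it as the whole cause of the changes as a set: they kept a median of 90.8% (88.5% to 92.7% with each sample left out), and standard errors widened by a median of 1.28 times, so lost precision could have ended calls. The smooth muscle list went the other way, its median falling from 1.69 to 0.29 (0.064 to 0.43 with each sample left out), so admixed tissue is a candidate source of its rise, and its part in single genes stays open.

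Genes called between arrays on different chips were checked on their other detected probes. The SEs given here are over genes, which share the same arrays, and leave out the spread between samples. The other probes changed by a median of 44.9% as much (SE 2.22) for NPK against NP and 40.2% (SE 2.01) for NPK against 1 month, under the bound of 50%, so probe-specific differences between arrays are a candidate cause of many of these calls. They changed by 77.4% as much (SE 1.91) for 3 months against 1 month on 1 chip, which argued against such differences there. For NPK against 3 months they changed by 63.6% as much (SE 1.63), above the bound. The 3-month arrays share the chip of the 1-month arrays, so this share cannot exclude probe-specific differences between chips there. For changes of at least and under 2-fold the medians were 43.0% (SE 4.01) and 45.3% (SE 2.50) for NPK against NP, neither under 50% by 2 SE with these fewer genes, 39.1% and 40.5% for NPK against 1 month, and 75.9% and 81.1% for 3 months against 1 month, so the lower shares did not follow from smaller changes. With the chip as a random block 2361 genes were still called between NPK and NP, though a difference shared by all chips of a genotype is not separated from genotype.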

How the results depend on the processing

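The alternatives with covariates, without NPK arrays rich in seminal vesicle transcripts (limit 10) with NP replicates 4 and 5 as 2 samples with chip means taken off a correlation and without Etv4 and Etv5 in their list were chosen only after the data were seen. Over all alternatives, called lists kept direction and side of the threshold in 735 cases, were weaker in 76 and turned in 1; named genes kept both in 3281, were weaker in 154, stronger in 8 and turned in 35. Among settings other than a single sample left out, named genes were weaker most often with the covariates (29) and on the chips of 1 barcode series (16). A fit of only the 2 groups weakened 13 and leaving out the chip of NPK 1 to 5 weakened 11. Etv4 and Etv5 rose between NP and NPK in 36 of 36 alternatives (0.86 to 2.30 and 0.57 to 1.53). Etv4 passed in 12 of 19 for 3 months against 1 month (1.07 to 2.95), and in 27 of 29 for NPK against 3 months. In the same 2 comparisons Etv5 passed in 4 of 19 (0.55 to 1.47) and 26 of 29, and Etv1 in 0 of 19 and 2 of 29. Of these 2 alternatives, 1 was a run with a sample left out, and the lowest limma adjusted p of Etv1 was 0.00179. The cause of the changes below was not tested unless fewer samples or a stricter threshold gave it. The chip as a random block (consensus correlation 0.182) gave 2361 genes for NPK against NP and 1407 for NPK against 1 month. For NPK against NP, 2765 genes passed without the chip of NP 6 to 8, 2114 without that of NPK 1 to 5, 1601 on chips of 1 barcode series (4 against 3 samples), 2164 with covariates and 2866 without the 4 NPK arrays rich in seminal vesicle transcripts. A minimum of 2-fold left 1176, and 782 for NPK against 1 month and 2865 for NPK against 3 months. A fit of only the 2 groups gave 1337 for 3 months against 1 month, and array weights 4563 for NPK against 1 month. With an estimated correlation 0 lists were called by camera in each comparison, with 4, 2, 0 and 2 at an unadjusted p under 0.05. For NPK against 1 month, lists called numbered 2 with no filter, 0 with the stricter detection filter, 2 with array weights, 5 without the chip of NPK 1 to 5, 3 with covariates and 3 without the NPK arrays rich in seminal vesicle transcripts; for NPK against 3 months, 8 under median scaling and 3 with that filter.

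Etv1 turned between NPK and NP under median scaling (-0.30) and without the chips of NP 1 to 5 (-0.20) or NPK 6 and 7 (-0.024). For NPK against 1 month Etv1 turned under median scaling (-0.15), the mean of probes (-0.66), the replicate block (-0.42), array weights (-0.13) and without the chips of NPK 6 and 7 (-0.058) or NPK 8 (-0.027). Etv4 turned there under median scaling (-0.085) and without the chip of NPK 1 to 5 (-0.17) or the rich arrays (-0.20), and Etv5 with covariates (0.18) and without the rich arrays (0.063). None of these was called. With covariates Pate14 (0.40), Ankrd37 (-0.23) and the hypoxia and glycolysis list (-0.079) turned at 3 months against 1 month, and Tnnc2 (0.99) for NPK against 1 month, which is built in, since Tnnc2 belongs to the skeletal muscle list used as a covariate.

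With each sample left out, genes numbered 3610 to 4324 for NPK against NP, 1108 to 2206 for 3 months against 1 month, 1576 to 2740 for NPK against 1 month and 2736 to 4949 for NPK against 3 months, and lists 11 to 14, 5 to 10, 1 to 5 and 4 to 5. The lowest gene counts came without 3-month replicate 1 (1108 and 2736) and 1-month replicate 2 (1576; 1629 without replicate 1). A lone 3-month sample was assumed to vary like the other groups. Changes were, for Etv1, -0.11 to 0.23 for NPK against NP, -0.38 to 2.08 for 3 months against 1 month, -0.24 to 0.18 for NPK against 1 month and -2.05 to 0.40 for NPK against 3 months. For NPK against 1 month Etv4 was -0.33 to 0.50 and Etv5 -0.47 to 0.26. The correlation across genes between the comparisons was -0.08 to 0.01. Not run were the authors' values for NPK against the month-labelled groups and lists under the robust prior. The chips of 1 barcode series held no month-labelled array, and other chips and rich NPK arrays were not left out for 3 months against 1 month. Signal over background limits dim genes. NPK arrays without a stage label detected 15855 to 18226 probes, against 19063 to 20405 on NP arrays and 19458 to 20138 on month-labelled arrays. Falls of dim genes in these NPK arrays are therefore not separated from array sensitivity.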

Other observations

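All values here were chosen after they were seen. Among 13 measured ETS factors, Elf3 and Spdef, which are known from epithelial cells, fell at 3 months against 1 month, with fitted changes of -2.68 and -2.69, Spdef being detected on 1 of 2 arrays at 3 months (limma adjusted p = 0.00300 and 0.000770), and Ets2 fell by 0.89, while Etv4 was higher. The list was not called in any comparison (adjusted p = 0.533 for NPK against NP and 0.823 for 3 months against 1 month). Its median for NPK against NP was -0.08, with a mean of 0.25 and an upward test direction. Of the mesenchymal transition genes, Vim rose by 2.72, Twist2 by 1.73, Zeb1 by 1.48 and Itga5 by 1.89 at 3 months, and 11 of 15 did not pass; the list was not called (adjusted p = 0.0502).

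Of the FOXO target genes, 5 of 17 were higher and 1 lower in NPK than in NP, with Klf2 at 1.11 higher and Sesn3, detected on 1 of 8 NPK arrays, lower, and the list was not called (adjusted p = 0.533). Squamous genes were lower in 3 of 12 cases, with Sprr1a at -1.34, Sbsn at -1.29 and Lor at -0.71 (list adjusted p = 0.110). Neuroendocrine genes were lower in 2 of 8 cases, Chga and Insm1, neither detected on any NPK array (list adjusted p = 0.466). NPK arrays detected fewer probes (15855 to 18226) than NP arrays (19063 to 20405). Lost detection in NPK is thus not separated from array sensitivity. The mean of the T and NK cell list was 8.59 ± 0.37 (SD, n = 7) in NP, 7.70 ± 0.32 (SD, n = 8) in NPK, 7.32 ± 0.19 (SD, n = 3) at 1 month and 6.72 ± 0.05 (SD, n = 2) at 3 months, where only 3 of 10 members were detected on at least 1 of 2 arrays. The list was not called for 3 months against 1 month (adjusted p = 0.381) or NPK against 1 month (adjusted p = 0.540).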
